A study of Homo sapiens with 2 samples.

How the data were processed

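The series holds 2 single-colour Agilent arrays, 1 of vehicle-treated and 1 of cisplatin-treated LNCaP xenografts. Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3 by an Arraystar kit. Per the file headers, scanning results were extracted with Feature Extraction 11.0.1.1 under protocol GE1_1100_Jul11, and the array design refers to build hg19 (GRCh37). Both arrays lay on the same slide and were scanned together. Whether tumours were collected, and RNA extracted and labelled, together is not given in the sources used here. The design text gives both 12 mice and a larger number for the study, and 12 per group is used here.

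The deposited scanner files hold intensity values per spot: a background-corrected processed signal, a median signal and a background median, with flags for outlier, saturated and background-level spots, per the file headers. The mean signal that the planned normexp setting calls for is not a column of these files, so the median signal was used in its place, a change made after seeing the data. The deposited annotated table and value table hold log2 values, which were equal to each other (largest difference 0). Compared with the scanner files, these log2 values were close to quantile-normalized log2 processed signals plus 0.11 to 0.12, with a largest deviation of 0.49 with vehicle and 0.25 with cisplatin. The authors' columns had medians of 7.61 with vehicle and 7.53 with cisplatin. How the authors filtered probes and with which tool they normalized is not given in the sources used here, and 2239 of their named probes were well above background on neither array.

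The main values are log2 of the processed signal minus the 75th percentile of the array over all 60691 probes, since 55.9% of probes were well above background on both arrays. Control spots and 41 outlier spots on each array were left out, and repeated spots were averaged. Probe names and gene coordinates came from the authors' table, with 23645 named probes and 16785 genes. Coordinates are given as that table prints them. Gene IDs of 23178 named probes were found in the RefSeq gene table of assembly GRCh38.p14, used for names only, and 2619 probes had an older symbol updated through it. The other 37046 probes had no gene name here. A gene is represented by its probe with the highest mean over both arrays, and counts as measured when that probe is well above background on both. For 12270 genes there was 1 probe.

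With 1 array per group no test was run and no p-value is given. Genes were counted at a difference of at least 2-fold (1 log2 unit). Gene lists were described by the median difference of their measured members and its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. Genes well above background on a single array have only a limit for their fold. Gene length is the distance between transcript start and end in the authors' table, and intervals over genes are bootstrap intervals, which describe genes of these arrays and not replicate tumours. Lists, comparisons and most alternative settings were fixed before the data were examined.

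Genes were named by a rule fixed in advance. It takes ICAM1 and NOTCH1, then the 12 largest differences each way among genes with official symbols whose probe is unsaturated, well above background on both arrays and at or above the median signal. These genes must differ at least 2-fold the same way under the main scaling, quantile normalization, normexp with quantile normalization and the authors' table. The rule adds the 2 highest and 2 lowest measured members of each list and up to 5 genes each way seen on 1 array only. Markers that set the signals against the known profile of LNCaP, HSPA1B and members of symbol families were chosen after their values were seen. Some genes that the rule takes are not reported here.

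The counts and percentiles were tested on simulated data drawn with the spread of the measured differences at like signal over 13441 genes. Of 200 genes given a log2 difference of 1, 51.5% were counted at 2-fold, and 99% of those given 2. A share near this 51.5% follows at any noise level, since symmetric noise was added to the threshold itself. It therefore does not measure how sensitive the counts are. Among simulated genes with no difference, 181 were counted higher and 188 lower, against 378 and 918 measured. The simulated noise was normal, centred on no difference, with its spread taken from the median absolute deviation. That measure gives little weight to extreme differences, so these counts do not show how many measured genes exceed noise. Lists of 25 genes shifted by 0.3 fell outside the central 95% in 95% of cases, and unshifted ones in 7.5%. Alternatives were scaling to another probe set or to the median, quantile and cyclic loess normalization, normexp with offset 50, the authors' tables, the mean of probes, and other filters on dim probes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.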

Results

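Gene expression was measured in xenograft tumours labelled as LNCaP, an androgen-responsive human prostate cancer cell line, grown under the skin of male NOD/SCID mice, a strain without functional T and B lymphocytes. The animals were not castrated. Cisplatin, a platinum drug that crosslinks DNA, was injected at 5 mg/kg at intervals of 3 d over a course of 30 d, and control animals received phosphate-buffered saline as vehicle, with 12 mice in each group. Total RNA from tumours of each group was labelled with Cy3 and hybridised to 1 single-colour Agilent array per group. Whether an array holds the RNA of 1 tumour or a pool was not given. With 1 array per group there were no replicates, so each difference below is a difference between these arrays, without a p-value, and the number of arrays limits the precision.

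Each array carried 60691 probes in addition to controls, and no spot was saturated. The signals of 34525 probes (56.9%) with vehicle and 42524 probes (70.1%) with cisplatin were well above background. The lowest such signal was 41.5 fluorescence units with vehicle and 22.4 with cisplatin. Spots printed repeatedly for the same probe had a median SD of 0.10 log2 units with vehicle and 0.08 with cisplatin, over 19 probes with 10 spots each. Names were at hand for probes of 16785 genes, and 13441 of these were measured well above background on both arrays. Values are log2 signals relative to the 75th percentile of the array, and a difference is cisplatin minus vehicle. The median difference over all measured genes was 0.14. Scaling to the median of the array instead lowers every difference by 0.21. Medians of gene lists below are not relative to all genes and are to be read against this 0.14. Bootstrap intervals of lists and shifts of symbol families are given relative to all genes.

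The title of the series names ICAM1 and NOTCH1, so these came first. ICAM1 encodes CD54, an adhesion receptor for leukocyte integrins, and lies at 10381516 to 10397291 on the plus strand of chromosome 19 (hg19). Its signal was 69.6 with vehicle and 158.3 with cisplatin, a 2.37-fold higher level with cisplatin (log2 difference 1.25). The gene rests on 1 probe of modest signal, and the difference was 0.67 after normexp background correction and quantile normalization. NOTCH1 and NOTCH2 were not analysed here. Among ICAM family members and partners, 9 of 12 measured genes lay above the all-gene median and ICAM1 alone was at least 2-fold higher. ICAM2 followed at 0.66, while the membrane linkers EZR and RDX were at -0.43 and -0.34. The group's median was 0.35, at percentile 95.7 of 10000 random lists matched on mean signal.

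Notch ligands, receptors and processing enzymes had a median of 0.25 (percentile 88.7), with 2 of 21 measured genes at least 2-fold higher and 0 lower. NOTCH4, a receptor, and APH1B, a gamma-secretase subunit, were both at 1.18. The ligand gene JAG2 and the gamma-secretase subunit gene NCSTN were at -0.94 and -0.92. Of 14 measured Notch target genes, 0 were 2-fold different in either direction, and their median was 0.30 (percentile 91.2). CCND1 and NRARP were highest at 0.96 and 0.95, and HES1 and HES4 lowest at -0.69 and -0.24. Stem and tumour-initiating cell markers went both ways. ALDH7A1 and ICAM1 were higher at 1.37 and 1.25, whereas ITGA6, the laminin receptor subunit CD49f, and ALDH1A3, a retinoic acid synthesising enzyme, were lower at -4.03 and -1.94. In all, 2 of 20 such markers were at least 2-fold higher and 4 lower, and the median of 0.05 lay at percentile 18.7.

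Across the 13441 genes measured on both arrays, 378 were at least 2-fold higher with cisplatin and 918 at least 2-fold lower. Higher genes thus made up 29.2% of these, against 12.6% with scaling to the array median and 13.2% with cyclic loess. Without a filter on dim probes the balance turned around, with 1315 genes higher and 1198 lower (52.3% higher). Lower genes were mostly of modest signal: among the 2688 brightest genes 55 were higher and 27 lower, and among the 2689 dimmest 71 were higher and 250 lower. The lowest signal well above background was a scaled log2 value of -3.37 with vehicle and -4.20 with cisplatin. Dim genes near these limits pass on both arrays more readily when lower with cisplatin than when higher, so the filter favours lower counts there. Among the 6721 genes at or above the median signal, 166 were higher and 261 lower. The genes named next were required to be bright and to differ at least 2-fold the same way under 4 normalizations, which 105 higher and 225 lower genes did. Where a gene had several probes well above background on both arrays, 161 lower genes were backed by a median of -0.81 for their other probes. For 74 higher genes the other probes had a median of 0.23, with a bootstrap interval of 0.13 to 0.43, which includes the median of all genes. The other probes of 8 of these genes were at least 2-fold higher, and those of 77 lower genes at least 2-fold lower.

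MYEOV, a gene often co-amplified with CCND1 in cancers, was 8.47-fold higher with cisplatin, at signals of 828 and 6724. HSPA1A, a stress-inducible chaperone gene, was 7.91-fold higher. The probe of its near-identical neighbour HSPA1B gave a log2 difference of -0.64, so the level of either gene is uncertain. TNF, the inflammatory cytokine gene, was 7.71-fold higher (3366 and 24899), and CD70, encoding a ligand of the TNF family, 7.10-fold. VSTM1 and CLEC4E, which encode receptors known from myeloid cells, were 6.80-fold and 5.72-fold higher. EGR4, an immediate early transcription factor gene, was 6.46-fold higher, and NOCT, a circadian nuclease gene, 4.69-fold. SLIT3, a guidance ligand gene, HS3ST4, a heparan sulfate sulfotransferase gene, and MT1E, a metallothionein gene, were 4.66-fold, 4.53-fold and 4.51-fold higher. ZFX, a zinc finger gene, was 5.13-fold higher by its brightest probe, but a further probe gave -0.07. All of these genes except ZFX rest on 1 probe.

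Among lower genes, SYT5, which encodes a synaptotagmin, had the largest difference, with a signal of 5185 with vehicle and 54.9 with cisplatin on its only probe, 90.5-fold lower. ITGA6 was 16.4-fold lower, and its probes gave -4.03 and -3.99. HIF1A, the oxygen-regulated transcription factor gene, was 8.21-fold lower (12188 and 1424), with probes at -3.04 and -2.99. TCEA1, a transcription elongation factor gene, was 8.14-fold lower, and its other probe gave -3.64. ERH, the splicing factor gene SRSF9 and ARGLU1, a gene tied to RNA processing, were 13.7-fold, 12.2-fold and 9.97-fold lower on 1 probe each. HSP90B1, the chaperone of the endoplasmic reticulum, was 9.33-fold lower (8202 and 843). ADAM9, a membrane metalloprotease gene, and SERINC1 were 9.26-fold and 8.48-fold lower. Probes disagreed for TMPO, a nuclear envelope protein gene, at -3.06 and 0.40.

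**Figure D1:**
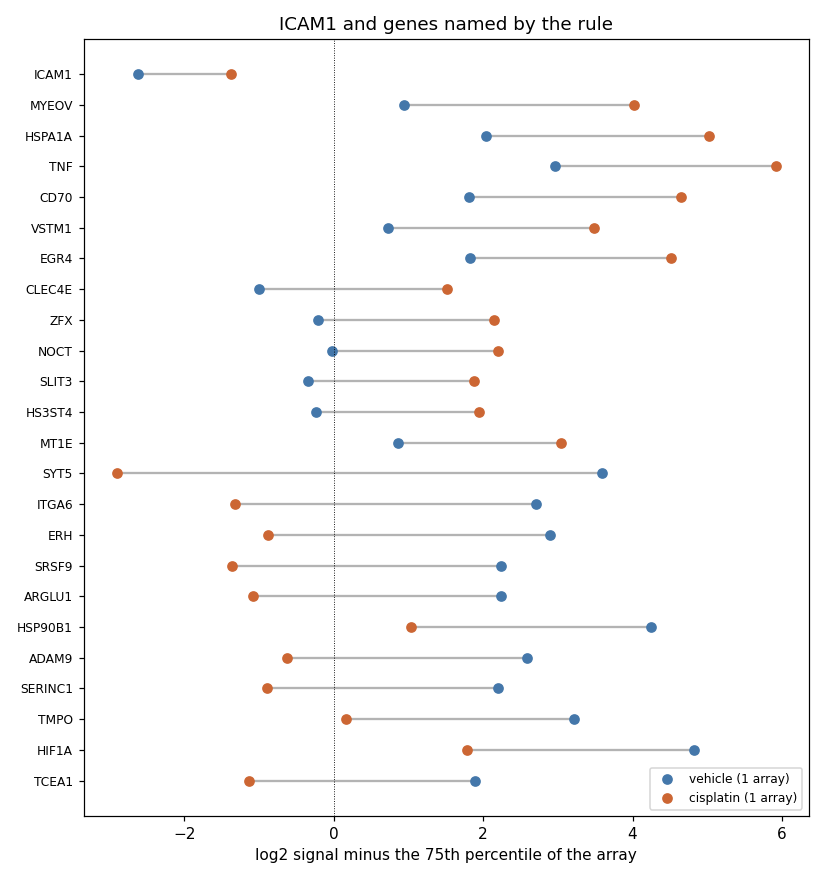
Normalized signal of ICAM1 and of genes named by size of difference, as log2 signal minus the 75th percentile of the array; each point is 1 array, with vehicle in blue and cisplatin in orange. SYT5 shows the largest gap, from 3.59 with vehicle to -2.91 with cisplatin, and TNF the highest level, 5.91 with cisplatin.

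Genes at least 2-fold lower with cisplatin were longer than others. Their median length was 43.4 kb, against 21.7 kb for all measured genes and 23.0 to 28.6 kb for the central 95% of random gene sets matched on mean signal. Genes at least 2-fold higher were shorter, with a median of 14.5 kb against 18.8 to 26.9 kb in matched sets. In the shortest decile 20 genes were lower and 72 higher, and in the eighth decile 164 were lower and 25 higher. In the decile of the longest genes the count of lower genes was 120.

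**Figure D2:**
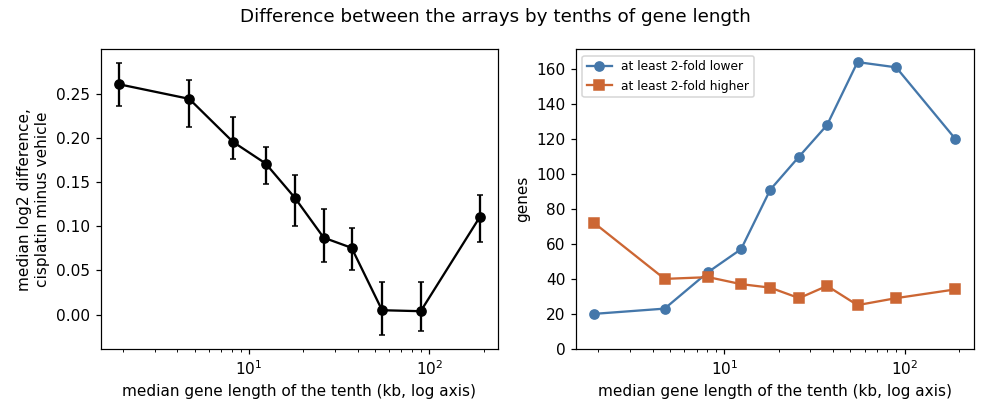
Left, median log2 difference (cisplatin minus vehicle) of measured genes in 10 groups of rising gene length, with 95% bootstrap intervals over genes; right, number of genes at least 2-fold lower or higher in each group, against median gene length in kb on a log axis. The median goes from 0.26 in the shortest group to 0.00 in the ninth and 0.11 in the longest.

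Gene lists were fixed before the data were examined, and 38 of them had at least 3 measured members. Of these 38, 11 had a median outside the central 95% of random lists, 8 above and 3 below. For lists of genes drawn at random, 1.9 are expected. That expectation treats genes as independent and does not cover variation between tumours. For 5 of these 11, the bootstrap interval over members of the shift from all genes included 0: basal prostate epithelium (-0.05 to 0.59), HLA class I (-0.10 to 0.40), heat shock proteins (-0.83 to 0.30), immediate early genes (-0.43 to 0.50) and skin keratinocytes (-0.06 to 0.71). Some lists share genes: ICAM1, IER3, CXCL1 and GDF15, for example, each stand in more than a single list. The list of long non-coding RNAs was not analysed here, because none of its members had a probe under its gene symbol.

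**Figure D3:**
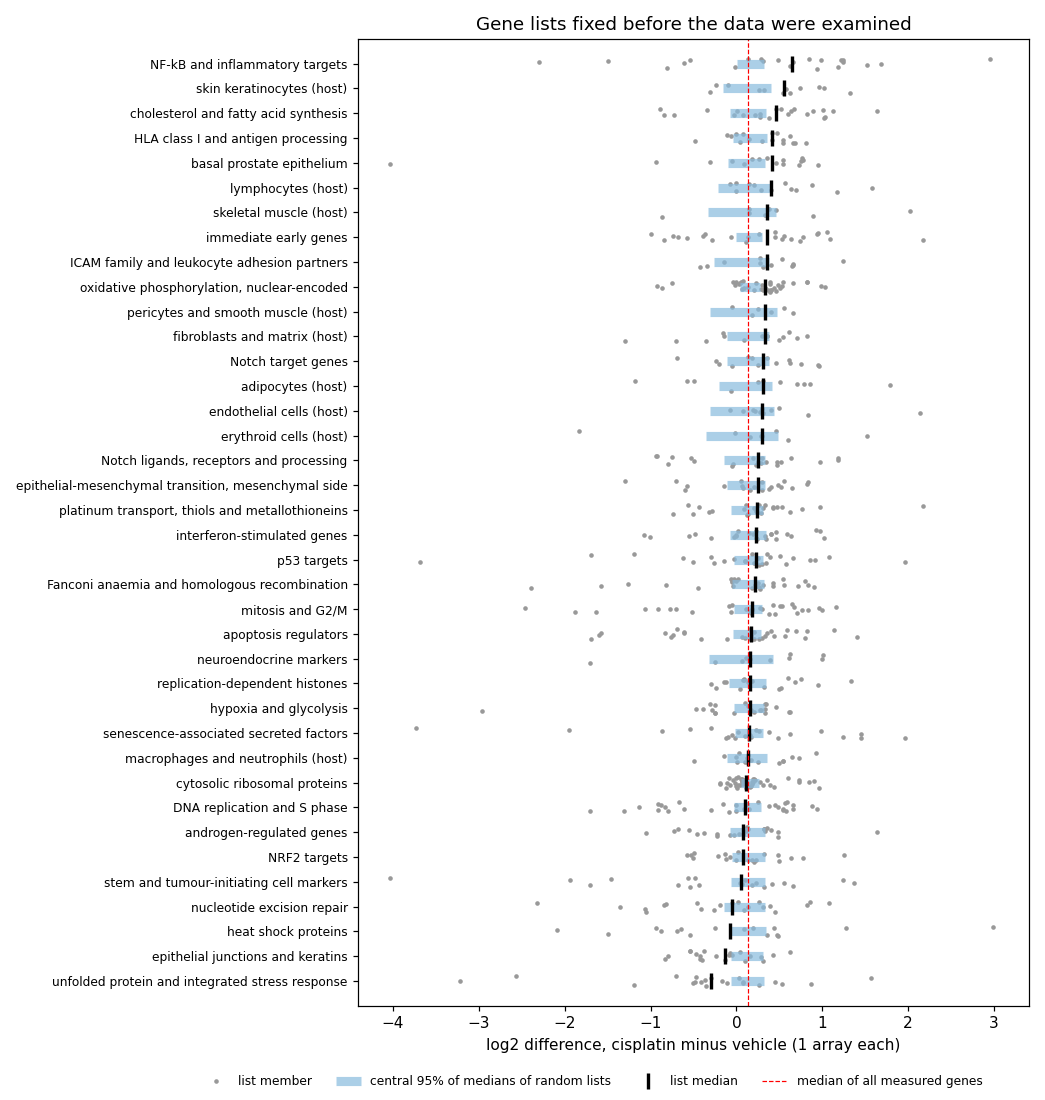
Log2 difference (cisplatin minus vehicle) of the measured members of each gene list (grey points), the list median (black tick) and the central 95% of medians of 10000 random lists matched on mean signal (blue bar); the dashed line is the median of all measured genes, 0.14. The highest median is that of NF-kB and inflammatory targets, 0.64, and the lowest that of the unfolded protein and integrated stress response, -0.30.

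NF-kB and inflammatory targets stood highest of all lists. Of 22 measured genes, 7 were at least 2-fold higher with cisplatin and 2 lower, and the median of 0.64 exceeded that of every matched random list (percentile 100). TNF and CXCL3, a neutrophil chemokine gene, were at 2.95 and 1.69. PTGS2, encoding the prostaglandin synthase COX-2, and TNFAIP2 went the other way, at -2.30 and -1.50. Immediate early genes had a median of 0.36 (percentile 99.7), but only 13 of 24 lay above the all-gene median. EGR3 and ZFP36 were highest at 2.17 and 1.09, and FOS was among the lowest at -0.84, as was DUSP6, with signals of 2576 with vehicle and 1236 with cisplatin. This list fell inside the central 95% with cyclic loess (percentile 95.6), with normexp (91.0) and without a filter on dim probes (87.2).

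Interferon-stimulated genes were spread around the all-gene median (0.23, percentile 78.3), with MX2 and OAS3 at 1.03 and 0.97 and IRF9 at -1.08. IFI44L had signals of 68.9 with vehicle and 33.0 with cisplatin. HLA class I and antigen processing genes had a median of 0.42 (percentile 99.6), although 0 of 17 were 2-fold different. ERAP2 and TAPBP were at 0.81 and 0.69, and CANX and TAP1 at -0.48 and -0.11. Under 5 of the 10 other settings this list lay inside the central 95%, with percentiles down to 90.4. These 5 include both of the authors' tables, which hold equal values. Senescence-associated secreted factors went both ways, with 4 of 24 at least 2-fold higher and 2 lower (median 0.15, percentile 51.8). GDF15, a stress-induced cytokine gene, and HGF were at 1.96 and 1.45, and IGFBP3 and MMP1, a collagenase gene, at -3.74 and -1.95.

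Unfolded protein and integrated stress response genes were lower as a group, with a median of -0.30 (percentile 0.050) and 5 of 21 members above the all-gene median. HSP90B1 was at -3.22 and DNAJB9, a co-chaperone of the endoplasmic reticulum, at -2.57, while CHAC1 and CRELD2 were higher at 1.57 and 0.87. The median of heat shock protein genes was -0.08 (percentile 2.22), with HSP90AB1 and HSPH1 at -2.09 and -1.50 but HSPA1A and HSPA1L at 2.98 and 1.27. The call for heat shock genes is marginal: under 7 of the 10 other settings the list was inside the central 95%, with percentiles up to 28.8. Part of this count reflects only the draw of random lists. Median scaling left the shift from all genes at -0.22, as in the main setting, and gave 2.5. The authors' tables hold equal values, yet gave 2.6 and 2.45. Targets of NRF2, the oxidative stress regulator, had a median of 0.08 (percentile 23.6), HMOX1 and TKT being highest at 1.25 and 0.77 and AKR1C3 and PGD lowest at -0.57 and -0.53.

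The genes most directly tied to cisplatin's action showed no common shift. Among p53 targets the median was 0.23 (percentile 80.3). GDF15 and XPC were higher at 1.96 and 1.08, PLK2 and FAS lower at -3.69 and -1.70, and in all 2 of 26 were at least 2-fold higher and 3 lower. Nucleotide excision repair genes, which remove platinum adducts, had a median of -0.05 (percentile 8.20), with 4 of 21 at least 2-fold lower. The bootstrap interval of their shift from all genes was wide, -0.60 to 0.13. RPA1 and GTF2H3 were at -2.32 and -1.36, and XPC and ERCC1 at 1.08 and 0.85. In the Fanconi anaemia and homologous recombination list, RAD54B and RAD51AP1 were lower at -2.39 and -1.58 and FANCA was at 0.84, around a median of 0.22 (percentile 80.6). Genes of platinum transport, thiols and metallothioneins had a median of 0.24 (percentile 84.9). MT1E and MT1A were highest at 2.17 and 0.97, and SLC31A2 was at -0.56. Apoptosis regulators had a median of 0.18 (percentile 69.2), with TNFRSF10A, a TRAIL receptor gene, and CFLAR at 1.40 and 1.13 and FAS and DIABLO at -1.70 and -1.60.

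Cell cycle genes likewise lay on both sides. The mitosis and G2/M list had a median of 0.19 (percentile 71.6), with 1 of 31 at least 2-fold higher and 4 lower. UBE2C and CDC25C were at 1.16 and 0.99, and the checkpoint kinase gene BUB1B and HMMR at -2.46 and -1.87. DNA replication and S phase genes had a median of 0.10 (percentile 31.4), with RRM1 and MCM6 at -1.71 and -1.31 and MCM10 at 0.88. Replication-dependent histone genes had a median of 0.16 (percentile 56.0), H2AC20 and H2AC11 being at 1.33 and 0.95 and H1-4 and H2BC5 at -0.29 and -0.24.

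Androgen-regulated genes lay close to all genes, with a median of 0.08 (percentile 25.9). STEAP2 was at 0.49, and KLF5 and SORD at -1.06 and -0.72. Epithelial junction and keratin genes were lower as a group without any member being 2-fold different. Their median was -0.13 (percentile 0.59), and 5 of 21 exceeded the all-gene median. CLDN7 and ESRP1, a splicing regulator of epithelial cells, were at -0.83 and -0.79, ESRP2 and KRT18 at 0.63 and 0.42. With the authors' normalized values the percentile was 2.85. The mesenchymal side of the epithelial-mesenchymal transition had a median of 0.25 (percentile 85.1), with SNAI1 and COL3A1 at 0.83 and 0.82 and FN1 and MMP2 at -1.30 and -0.70. Markers of basal prostate epithelium had a median of 0.41 (percentile 99.6), TP63 being at 0.78 and ITGA6 and JAG2 at -4.03 and -0.94. This group was at percentile 58.0 when the probes of each gene were averaged. Neuroendocrine markers were at a median of 0.16 (percentile 58.7), with NKX2-1 and DDC at 1.01 and 0.99 and SOX2 and SNAP25 at -1.70 and -0.25.

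Signals of several genes did not match what is known of LNCaP cells. GSTP1, silenced in LNCaP, gave 58815 with vehicle and 68777 with cisplatin. The basal keratin gene KRT14 gave 68419 and 53083, CAV1 11525 and 16128, CD44 7740 and 11692, KRT5 900 and 1256, and TP63 216 and 356. FOLH1, encoding prostate-specific membrane antigen, was not well above background with vehicle (28.5) and gave 48.3 with cisplatin. Prostate genes TMPRSS2 (6683 and 8005) and KLK3 (812 and 736) were well above background on both arrays.

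Cholesterol and fatty acid synthesis genes were higher as a group. With 5 of 23 at least 2-fold higher and 0 lower, their median was 0.46 (percentile 99.8). IDI1, an isomerase of the isoprenoid pathway, was at 1.13, while DHCR7 was at -0.84. Nuclear-encoded oxidative phosphorylation genes had a median of 0.33 (percentile 99.8), and 24 of 37 exceeded the all-gene median. ATP5MC1 and SDHA were highest at 1.04 and 0.99, and UQCRC1 and NDUFS1 lowest at -0.92 and -0.87. ATP5MC1 was at -0.23 when its probes were averaged, and the list was at percentile 97.3 after normexp. Hypoxia and glycolysis genes had a median of 0.15 (percentile 50.2), with PGK1, a glycolytic kinase gene, and HK2 at -2.96 and -0.47 and ENO2 and LDHA at 0.63 and 0.61. Of 43 cytosolic ribosomal protein genes, 0 were 2-fold different (median 0.12, percentile 20.1). RPL14 and RPL6 were highest at 0.96 and 0.90, and RPLP2 and RPL8 lowest at -0.19 and -0.19.

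Markers of cells that a mouse host could add were read with human probes, which may or may not bind mouse transcripts. Skin keratinocyte genes had a median of 0.56 (percentile 99.9) and 9 of 12 lay above the all-gene median, with IVL and SPRR2A at 1.32 and 1.02 and KRT14 and DSG3 at -0.31 and -0.24. Lymphocyte genes had a median of 0.40 (percentile 97.9), with CD79A and CD8A at 1.58 and 1.17 and MS4A1 and LCK at -0.08 and -0.01. The mouse strain lacks functional T and B lymphocytes, so this shift is not evidence of such host cells. Its source was not tested. The lymphocyte list was at percentile 93.9 when random lists were matched on gene length as well, and at 97.45 with the authors' normalized values. The authors' value table, which holds equal values, gave 97.85 with another draw of random lists. Macrophage and neutrophil genes had a median of 0.13 (percentile 46.4), ADGRE1 and CD68 being at 0.93 and 0.73 and S100A8 and S100A9 at -0.50 and -0.14. For endothelial genes the median was 0.30 (percentile 86.3), with ROBO4 and EGFL7 at 2.14 and 0.83 and NOS3 and ERG at -0.08 and 0.07. Fibroblast and matrix genes were at 0.33 (percentile 93.5), with COL3A1 and COL6A2 at 0.82 and 0.70 and FN1 and MMP2 at -1.30 and -0.70.

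Pericyte and smooth muscle genes had a median of 0.33 (percentile 87.5), with CSPG4 and ACTA2 at 0.66 and 0.56 and NOTCH3 and MYL9 at -0.05 and 0.19. Adipocyte genes were at 0.30 (percentile 87.1), with CFD and PLIN4 at 1.78 and 0.86 and LPL and FABP4 at -1.18 and -0.57. Skeletal muscle genes were at 0.36 (percentile 91.6), with TPM2 and ACTA1 at 2.02 and 0.89 and TNNT3 and TNNI2 at -0.86 and 0.14. Erythroid genes were at 0.29 (percentile 79.2), with SLC4A1 and HBM at 1.52 and 0.61 and HBA2 at -1.83.

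A further 1970 genes were well above background with cisplatin only and 177 with vehicle only, so their folds are lower limits. Each limit sets the brighter signal against the higher of the dim probe's own signal and the lowest signal well above background on the other array. CD40, a receptor of the TNF family, was at least 10.3-fold higher with cisplatin, followed by SART1 (at least 9.07-fold), RNF41 (8.42-fold), TIGD7 (7.76-fold) and TM4SF19 (6.91-fold). LNX2 was at least 52.7-fold lower with cisplatin, RGS8, a regulator of G-protein signalling, at least 31.3-fold, KIF27 23.8-fold, NCAPG, a condensin subunit, 19.9-fold, and TCHP 18.95-fold. The limit reached 2-fold for 131 of the genes seen with cisplatin only and for 167 of those seen with vehicle only. With 1 signal limit for both arrays, an alternative chosen after seeing the data, the counts were 889 and 424.

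Among probes without a gene name, only those labelled by ultraconserved region or by HOX gene cluster were compared here. Whether the transcripts bound by the ultraconserved region probes are non-coding was not tested. Of 398 such probes well above background on both arrays, 9 were at least 2-fold higher with cisplatin and 30 lower. All 30 lower probes were ultraconserved region probes, of which 262 were measured. Some regions count with both a + and a - probe, such as uc.208 and uc.481, so these probes are not all separate regions. Among 136 measured HOX cluster probes, 2 were higher and 0 lower.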

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

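Most probes without a gene name in the tables used here form a part of the arrays that no comparison above draws on. Of 37046 such probes, 1174 are the ultraconserved and HOX cluster probes described above, 54 are other custom probes and 60 are labelled as negative. Of the remaining 35758, 15759 were well above background on both arrays. Signals at least 2-fold higher with cisplatin were found for 487 of them, and signals at least 2-fold lower for 644. They stand out only as a signal in data outside the main comparison, and which transcripts they bind was not analysed here.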

How the results depend on the processing

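Alternatives chosen after seeing the data were normexp on the median signal, the common signal limit, the requirement on all probes of a gene and the match on gene length. The count of genes at least 2-fold higher with cisplatin, 378, was 185 with median scaling, 203 with cyclic loess, 164 with normexp, 1315 without a filter on dim probes (with 1198 lower, so that higher genes were then the more numerous), 166 in the brighter part of genes and 8 when all of at least 2 probes had to agree. The count of lower genes, 918, was 261 in the brighter part and 72 when all probes had to agree; these last settings examine fewer genes by construction. Genes well above background with cisplatin only, 1970, numbered 564 with the positive-and-significant flag and 889 with a common signal limit, and those with vehicle only, 177, numbered 71 and 424. ICAM1, at 1.25, was at 0.67 after normexp and between 0.92 and 1.21 under the other scalings and the authors' tables. ATP5MC1, at 1.04, was at -0.23 with the mean of probes. Ultraconserved and HOX cluster probes at least 2-fold different were 217 without a filter. For changes other than fewer genes examined, the cause was not tested. Among single genes and the lists inside the central 95%, 1513 of the alternative values stayed close to the main value, 42 moved and 1, that of ATP5MC1, changed sign. All 11 lists outside the central 95% kept the sign of their shift from all genes in every alternative run. Scaling to the median or to another probe set subtracts a constant per array, so those runs could not change this shift. The authors' tables hold equal values but count as separate runs throughout. With random lists matched on gene length too, 12 lists lay outside, 10 of those 11 among them, joined by fibroblast and ribosomal protein genes at percentiles 97.9 and 1.41. Signal close to background limits what can be said of dim genes. The lowest signal well above background, 41.5 with vehicle and 22.4 with cisplatin, could affect the count of genes seen with cisplatin only. These unequal limits could also shift the balance of higher and lower genes among dim ones. Across 32 blocks of the array surface, median differences lay between 0.08 and 0.34. No paired analysis was possible because each group holds 1 array. The authors' table was not run for ultraconserved and HOX cluster probes, which it does not name.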

Other observations

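Tests of the detection limit, of gene length and of cell line markers were chosen after those results were seen; the test of symbol families was set before its result. Genes that share a symbol prefix were also grouped, and some of these families, HSPA among them, overlap the lists above. Of 119 families with at least 12 measured genes, 26 had a median outside the central 95% of random sets, 17 below and 9 above. Families named here were chosen after their values were seen. TAF genes, mostly subunits of the transcription factor TFIID, lay -0.43 from all genes with 5 of 23 at least 2-fold lower. Among these were TAF2 at -1.85 and TAF1A, which is not a TFIID subunit, at -2.38. Integrator subunits (INTS) lay at -0.56, with INTS13 at -1.60 and INTS3 at -1.20. Nucleoporins (NUP) lay at -0.49, with NUP133 at -2.05, and the splicing factors of the SRSF family at -0.40, with 4 of 12 lower, SRSF9 at -3.61 and SRSF1 at -1.59. PRPF splicing factors lay at -0.53 and PSMD proteasome subunits at -0.27. HSPA chaperones had the lowest shift, -0.78, with HSPA13 at -2.60 and HSPA1A at 2.98.

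On the other side, keratin-associated proteins (KRTAP) lay 0.27 above all genes, keratins (KRT) 0.19, CCL chemokines 0.34, the TIMM import subunits of mitochondria 0.28, gamma-protocadherins (PCDHGA) 0.42 and RNA polymerase subunits (POLR) 0.17. PCDHGA genes share exons and KRTAP genes resemble each other, so their probes may not be independent. The signs of the shifts named here were the same under quantile normalization, cyclic loess and normexp. The 26 families are 21.9% of those examined, with an exact binomial interval of 14.8% to 30.4%, where 5% is the chance value for independent families. The random sets were matched on mean signal but not on gene length, with which the differences varied. This share therefore cannot tell a joint shift of families from the trend with length. The hypothesis that families moved together stays untested beyond these arrays.

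Far more genes were well above background with cisplatin only than with vehicle only, a ratio of 11.1. A higher detection limit on the vehicle array is a candidate explanation. With 1 common signal limit the ratio was 2.10, and the lowest signal well above background was 41.5 with vehicle and 22.4 with cisplatin. The remaining excess was not resolved, and an effect of the drug stays open.

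Genes at least 2-fold lower with cisplatin were long. Noise of single probes is argued against as the source of the lower values for genes with at least 2 probes. Their other probes had a median of -0.81 (interval -1.09 to -0.65). The length of these genes was not examined separately, and genes with 1 probe stay open. A dependence on signal brightness is argued against by the median length of 43.4 kb, which lay above all 1000 random sets matched on signal. A loss growing with length, as transcription blocked along the gene could give, stays open over the first 9 deciles, whose medians fell from 0.26 to 0.00 (Spearman rho over all genes -0.19); only its growth into the longest decile is argued against, since that median was 0.11 above the ninth (interval 0.06 to 0.14). RNA integrity, probe position and base composition stay open as untested, as does another effect of the drug.

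Markers at odds with LNCaP were found on both arrays. All 6 of GSTP1, CD44, CAV1, KRT5, KRT14 and TP63, which LNCaP is known not to express, were well above background on both arrays. RNA of other human cells in both samples might give this, yet the genes were chosen for their signals and most named probes pass that flag, so the test decides nothing. Mouse skin RNA bound by the human probes could also contribute. Of 14 skin keratinocyte genes with a named probe, 12 were measured on both arrays. So were 13441 of all 16785 genes, so this count decides nothing either. Signals with vehicle and cisplatin were 68419 and 53083 for KRT14, 1726 and 1984 for LORICRIN and 192 and 229 for KRT10. KRT14 and KRT5 also stand in the basal prostate list, and without probe sequences these sources cannot be told apart. Whether the tumours were LNCaP at all was not tested and stays open; if they were not, every value above describes other cells.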
